A study of Homo sapiens with 6 samples.

How the data were processed

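The series holds total RNA from human myometrial stem cells treated for 3 h with CCT251545 or DMSO, with 3 libraries per group. Per the labels' protocols, ribosomal RNA was removed, strand-marked libraries were made, and 50 bp single reads were sequenced on one instrument type. The deposited values are raw read counts per gene symbol for 23228 genes, which the authors did not normalize. Per the submitters' processing notes, TopHat2, R 3.6.3 and the hg19 build were used, with no roles given. The counting program, its strand setting, the gene annotation and any filters are not given in the sources used here, so genes that overlap or share near-identical copies may exchange reads. The 5 summary entries of the table, for reads without a single gene, made up 36.6 to 38.9% of all entries and were left out of library sizes and tests. Among uniquely placed reads, those outside annotated genes made up 12 ± 0.278% with inhibitor and 12.7 ± 0.209% with vehicle (mean ± SD, n = 3; exact two-sided permutation p = 0.1, the smallest this design allows). No genome position is printed, because the reference used here is of another build.

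Columns were tied to samples by the group and number in their names. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 11.9 to 100.3 over 15 pairs). Genes were filtered with filterByExpr, leaving 13670, and scaled by the TMM method in edgeR 4.0.16 under R 4.3.3. The planned test was edgeR's quasi-likelihood test with robust priors and group as the only term, two-sided, with Benjamini-Hochberg adjustment at 0.05 over all tested genes. Standard errors of single genes are the absolute log2 change divided by the square root of the F statistic. Those of the median or mean of a gene set were taken over its member genes. Such genes are not independent, so these errors do not measure the spread between samples. CPM are TMM-normalised. The log2 values for list tests, components and pair differences used a prior count of 2.

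Same-numbered libraries deviated together from their group means (correlations 0.24, 0.46 and 0.69, each above the bound of 0.1 set for pairing), so a fit with the replicate number as a block is given beside the planned one. The pairing comes from the data alone. Inhibitor 1 correlated more closely with vehicle 2 (0.33) than with vehicle 1, and inhibitor 2 with vehicle 1 (0.18) also exceeded the bound. The bound therefore cannot show which of the libraries numbered 1 and 2 belong together.

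Before the data were examined, 33 gene lists, the rule for naming genes, the tests and most alternatives were fixed. The rule named up to 10 genes per direction with the largest log2 change among those that passed, with a mean log2 CPM of at least 1 and no overlap between the groups' libraries, leaving out pseudogenes, small RNAs and uncharacterised loci; all kinase module genes; and up to 4 members of each list with the smallest p. It was applied to the planned and the blocked fit, and other genes named were chosen after their values were seen. Lists with at least 5 tested members, 30 in number, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The endothelial and leukocyte lists had too few tested members, and none of the mitochondrial genome's genes was in the table. The result of 1 of the tested lists is not reported here. Genes that could bear on a donor's sex were left out of every test; leaving them out of the tests, and not of the names alone, was decided after the first fit.

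In simulated counts with 200 changed genes among 13670, averaged over 5 runs, the planned fit found 18.8, 62.1 and 91.8% of genes changed 1.5-, 2- and 4-fold, with 8.40% of its calls false. The blocked fit found 68.7, 89.9 and 94.5%, with 7.65% false. Counts for each fit were drawn from that fit's own model and dispersions, so the pairing was true by construction in the blocked runs. These rates therefore neither test the pairing nor rank the fits. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters and priors, a 1.2-fold threshold, and each library or pair left out. Offsets for transcript length and GC content, fitted per library with mgcv 1.9.3, were added after seeing the data, first with each gene's longest GENCODE transcript and later also with its principal transcript.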

Results

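Total RNA was sequenced from human myometrial stem cells, progenitors of the smooth muscle wall of the uterus, after 3 h with CCT251545 or with its solvent DMSO (vehicle). CCT251545 inhibits CDK8 and CDK19, the alternative kinases of the Mediator kinase module, which links transcription factors to RNA polymerase II. Each of the 2 groups held 3 libraries, numbered 1 to 3. Reads assigned to genes came to 24654101 to 34796983 per library, so that 3 counts, taken as the detection floor, correspond to 0.0862 to 0.122 CPM (counts scaled to library size). This floor covers counting error only. The submitters call the samples independent, but no label ties a sample to a separate donor or culture, so p-values measure the spread between these samples, which may be technical. The single comparison the design gives is inhibitor against vehicle, which asks which transcripts move within 3 h of blocking the kinases.

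The number 3 pair of libraries stood apart from the other 4 libraries on the first principal component, which held 51.4% of the variance. The deviations of same-numbered libraries from their group means correlated at 0.24, 0.46 and 0.69 across genes, but inhibitor 1 correlated more with vehicle 2 (0.33). As all 3 same-number values exceeded the bound of 0.1 set for pairing, results are given from 2 fits. The planned fit has group as its only term, and the other also takes the number as a block. The values across numbers 1 and 2 (0.33 and 0.18) exceeded the bound too. The bound thus sets the number 3 libraries apart but does not establish the pairs 1 and 2, on which the block also rests. A block of number 3 alone called 61 genes.

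**Figure D1:**
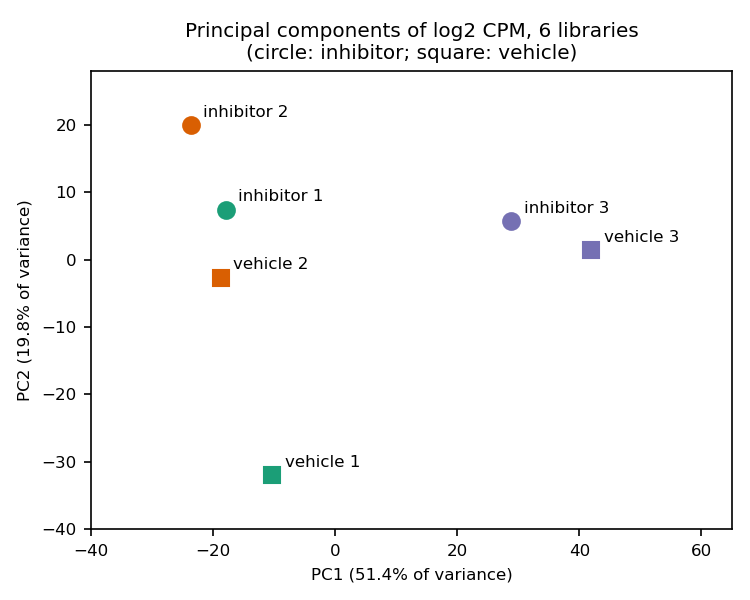
Principal components of log2 CPM over the tested genes, in arbitrary units, with the share of variance on each axis. Circles are inhibitor and squares vehicle libraries, and colour gives the replicate number; the 2 libraries numbered 3 lie at 28.8 and 41.9 on the first component and the other 4 between -23.7 and -10.4.

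In the planned fit 1 of 13670 tested genes passed, NOG, which encodes the secreted BMP antagonist noggin. NOG rose from 14.1 ± 0.907 to 34.6 ± 2.84 CPM (mean ± SD, n = 3), a log2 fold change of 1.30 ± 0.13 (SE), with an adjusted p of 0.0406 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p below 0.05 this fit gave 424 of the 13670 genes, a smaller share than the 0.05 that no change at all would give. With adjustment DESeq2 called 18 and limma-voom 0. With the replicate block, 180 genes passed in edgeR, 113 higher and 67 lower with the inhibitor, and NOG was among them (adjusted p = 1.07e-06). Among these 180 genes the median absolute log2 change was 0.55, all 180 moved the same way in the 3 pairs, 8 rose and 17 fell at least 2-fold. In 109 of them the libraries of the groups did not overlap, as in 7.88% of all tested genes, where chance gives 10%. The blocked test selects genes for differences that agree between pairs. The shared direction and the non-overlap of the 180 follow largely from that selection and are no separate support. Scaled by library totals alone, the blocked fit gave 105 higher and 100 lower. The blocked count was 284 without pair 1, 11 without pair 2 and 199 without pair 3, and NOG lost its call in the planned fit when any single library other than vehicle 3 was left out.

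**Figure D2:**
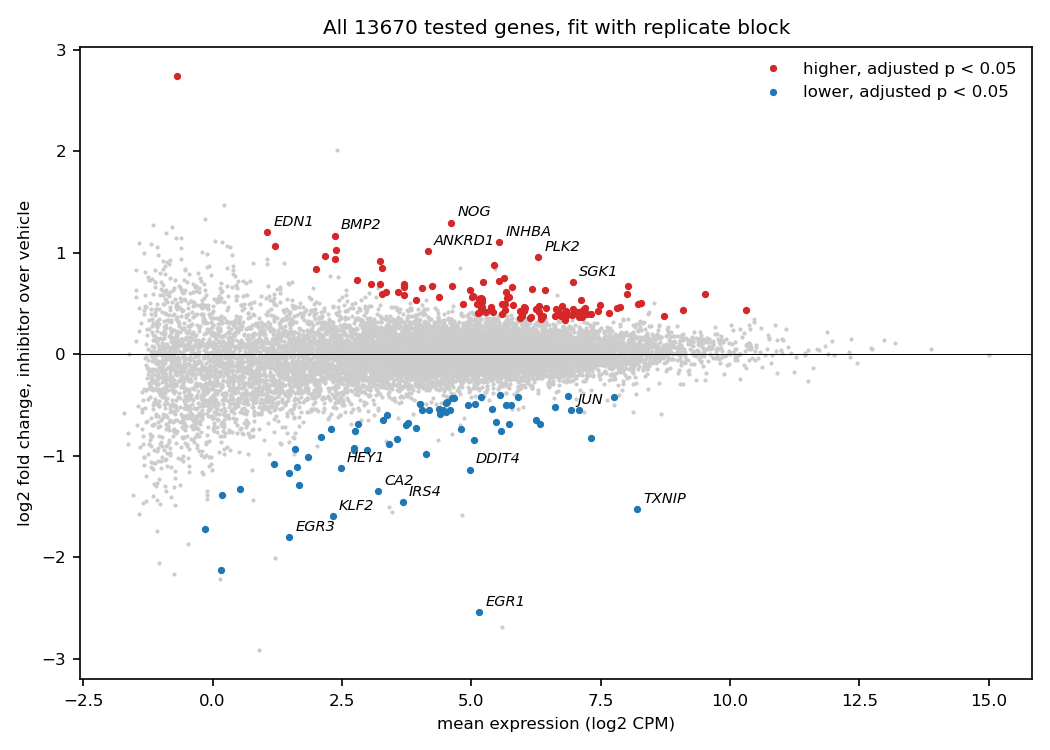
Log2 fold change (inhibitor over vehicle, replicate block) of each tested gene against its mean expression in log2 CPM. Coloured points are the 113 higher and 67 lower genes with an adjusted p below 0.05; EGR1 is the most reduced of the labelled genes and NOG the most increased.

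The largest reduction among the 67 genes that fell in the blocked fit was in EGR1, one of the immediate-early genes. Cells switch such genes on within minutes of a growth factor, and many of them encode transcription factors. EGR1 was 5.81-fold lower with the inhibitor (61.1 ± 34.8 CPM in vehicle, 9.79 ± 2.81 with inhibitor, n = 3; log2 change -2.54 ± 0.15, edgeR adjusted p = 1.07e-06). EGR3 was 3.49-fold lower (adjusted p = 0.000411) and KLF2, a shear-responsive zinc finger factor, 3.02-fold lower (adjusted p = 2.43e-05). JUN fell from 145 ± 12 to 98.7 ± 3.62 CPM (adjusted p = 0.000762), and MAFF, ATF3, CSRNP1 and IER3 also fell. In the planned fit the adjusted p was 0.328 for EGR1 and 0.0952 for KLF2. SRF, the serum response factor itself, rose by a log2 change of 0.44 ± 0.10 (adjusted p = 0.0190). Of 31 tested members of the list, 28 had a lower estimate with the inhibitor; in the blocked fit 8 fell, 1 rose and the other 22 did not pass, among them FOS (log2 change -1.43 ± 0.37, adjusted p = 0.0673). Adjusted over the list alone, 17 fell and 2 rose with the block, and 8 fell and 1 rose in the planned fit, where none passed over all genes. As a set the list was lower than other genes (camera, adjusted p = 2.11e-12 at the preset and 0.0405 at an estimated correlation). It also moved downward on its own (fry, adjusted p = 0.0190). With the replicate block the adjusted p was 0.514 with an estimated correlation and 0.119 in fry. Splits of the libraries other than the real one gave similarly low preset-correlation values for other lists (proliferation, camera adjusted p = 2.63e-13). The size of the preset-correlation value alone therefore does not mark an effect of the inhibitor.

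**Figure D3:**
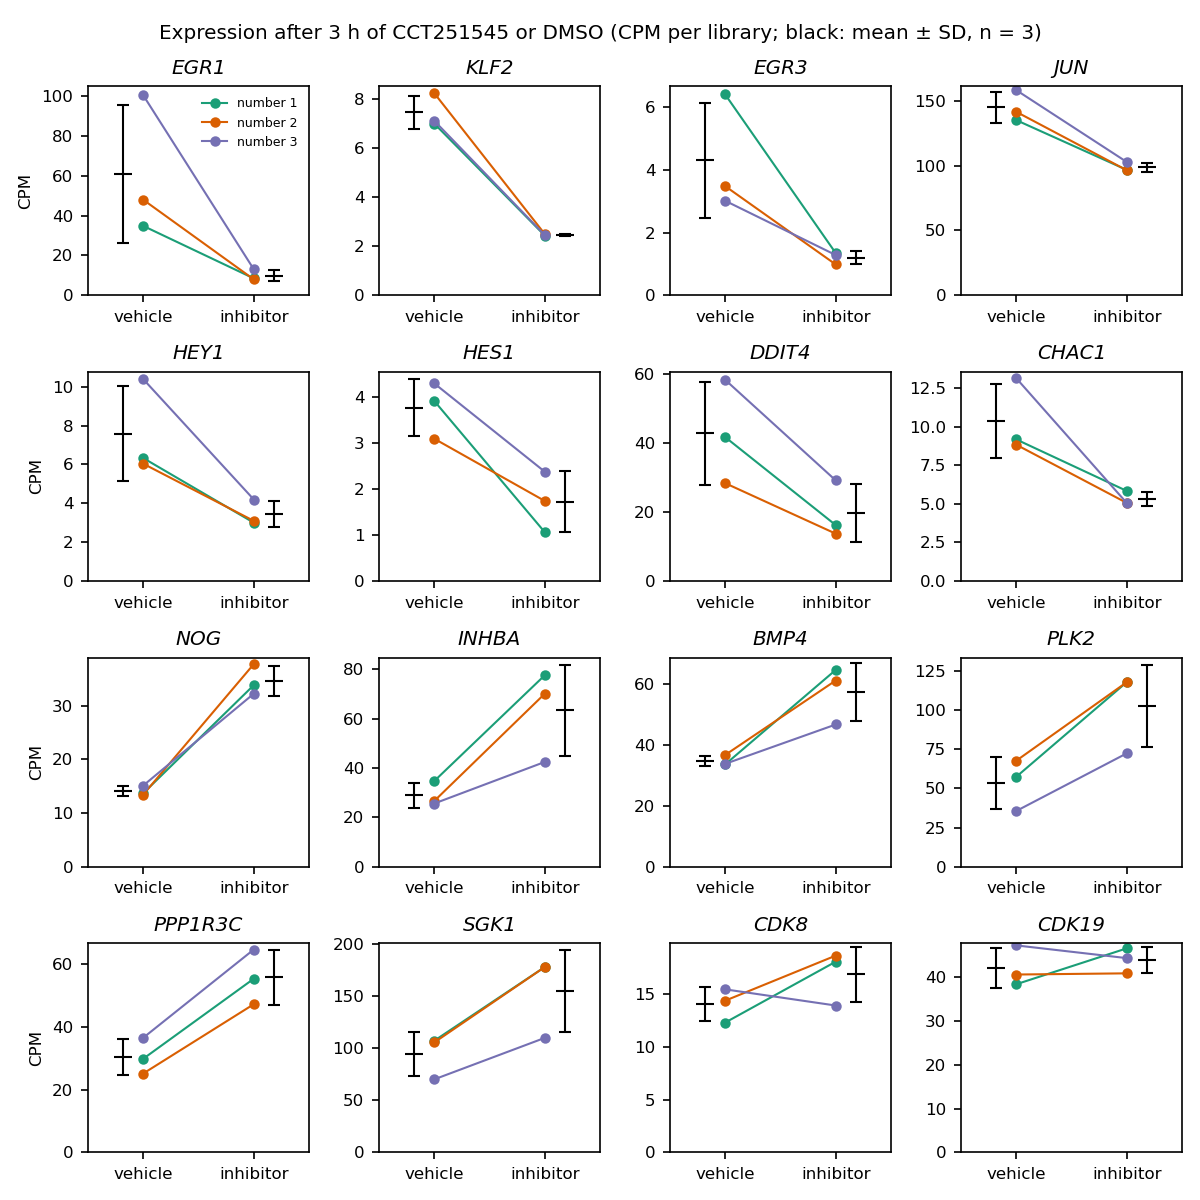
CPM of 16 named genes in each library, with lines joining same-numbered vehicle and inhibitor libraries and black marks at mean ± SD (n = 3 per group). In EGR1, KLF2, EGR3 and JUN each line falls and in NOG, INHBA, BMP4 and PLK2 each line rises, while the lines of CDK8 and CDK19 run both ways.

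In the list of ERK feedback genes 3 of 16 tested members fell and 1 rose. PHLDA1, DUSP6, which encodes a phosphatase of ERK, and SPRY4 fell in the blocked fit, with log2 changes of -0.69 ± 0.12, -0.55 ± 0.14 and -0.47 ± 0.11 and edgeR adjusted p values of 0.0105, 0.0462 and 0.0372. DUSP5, another ERK phosphatase, rose (0.44 ± 0.09, adjusted p = 0.0143). Of 16 members 13 had lower estimates (camera adjusted p = 0.000600; adjusted p = 0.487 with an estimated correlation), and adjusted over the list alone 6 fell and 1 rose with the block and 0 passed without it.

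In the list of ATF4 stress response genes 4 of 21 tested members fell in the blocked fit and 0 passed in the planned one. DDIT4, which restrains mTORC1, was 2.20-fold lower (42.8 ± 15 CPM in vehicle, 19.7 ± 8.29 with inhibitor, n = 3; edgeR blocked adjusted p = 1.93e-06), and CHAC1, a glutathione-degrading enzyme, 1.92-fold lower (adjusted p = 0.00434). TRIB3 and DDIT3 (CHOP) fell by log2 changes of -0.54 ± 0.12 and -0.48 ± 0.12. Of the 21 members 18 had lower estimates, and adjusted over the list alone 7 fell with the block and 1 without it. The set result was an adjusted p of 3.08e-05 in camera (adjusted p = 0.487 with an estimated correlation).

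Among inflammatory transcripts, none of 23 tested NF-κB targets passed over all genes, although 21 had lower estimates, and adjusted over the list alone 5 fell with the block and 2 without it. LIF was at 42.4 ± 20.6 CPM in vehicle and 13.8 ± 4.88 with inhibitor (blocked adjusted p = 0.306), and IL6 at 26.5 ± 7.88 and 14.4 ± 1.37 (adjusted p = 0.0602). For this list camera gave an adjusted p of 3.67e-08 (adjusted p = 0.234 with an estimated correlation), and without vehicle 2 the mean log2 change of -0.86 became -0.45 while the median of -0.24 became -0.32. SOCS3, a STAT3-induced feedback inhibitor, fell (adjusted p = 0.0122); the STAT3 list of 13 had a camera adjusted p of 0.0263 (adjusted p = 0.763 with an estimated correlation), which was 0.0682 with the replicate block. That call also ended without pair 1 or 3 (adjusted p = 0.112 and 0.110), inhibitor 1 or 2 (0.210 and 0.0973) or vehicle 3 (0.327). Adjusted over the list alone 3 fell and 1 rose with the block, and 2 fell without it.

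In the fixed list of secreted growth factors, 3 members rose and 1 fell, all of the TGF-β superfamily. INHBA, the activin A subunit, went from 29 ± 4.99 to 63.4 ± 18.5 CPM (2.15-fold, edgeR blocked adjusted p = 1.31e-05), BMP4 from 34.6 ± 1.73 to 57.3 ± 9.49 CPM (1.64-fold, adjusted p = 0.000481), and BMP2 rose by a log2 change of 1.17 ± 0.21 (adjusted p = 0.00466). GDF15, a stress-induced member of the same family, fell (-0.68 ± 0.16, adjusted p = 0.0383). These 4 were the only ones of 23 tested growth factors to pass with the block, 14 of the 23 had lower estimates (median log2 change -0.08), and 4 rose and 4 fell adjusted over the list alone. Of 16 BMP target genes NOG and ATOH8 rose and HEY1 fell, so 3 passed and they moved in both directions; adjusted over the list alone 4 rose and 2 fell. Neither list moved as a set in camera (adjusted p = 0.786 and 0.665). Mixed fry, which counts changes in either direction, passed the BMP list (adjusted p = 0.000939, and 0.00557 with the block). The growth factor list did not pass in it (adjusted p = 0.148, and 0.110 with the block).

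Of 11 tested Notch pathway transcripts 3 passed in the blocked fit, in both directions. The Notch ligand JAG1 rose from 67.5 ± 8.77 to 105 ± 15.4 CPM (edgeR blocked adjusted p = 0.0190), and the Notch effectors HEY1 (2.18-fold lower, adjusted p = 0.00129) and HES1 (2.25-fold lower, adjusted p = 0.0184) fell. HES1 lay at only 1.06 to 4.29 CPM. With 1 pair left out, its call held in 0 of 3 fits, and those of HEY1 and JAG1 in 2 each. HES4, another effector of the HES family, had a higher estimate without passing (0.76 ± 0.20, adjusted p = 0.0610). The other 7 members did not pass either, and camera gave an adjusted p of 0.139, or 0.0682 with the replicate block. The list passed as lower without inhibitor 3 (adjusted p = 0.0158), without vehicle 1 (0.0344), with a block of number 3 alone (0.0243), and with the replicate block without pair 1 (0.0168). With a stricter filter, a CPM of at least 1 in 3 libraries, 8 members were left and the camera adjusted p was 0.467. Without pair 3 it was 0.427. In each of these 2 settings the median log2 change was -0.08, against -0.31 in the planned fit, so the downward shift depended on low-count members and on pair 3. Adjusted over the list alone 2 rose and 3 fell with the block.

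Among smooth muscle contractile genes 1 passed. MYOCD, the coactivator of SRF that drives the smooth muscle programme, rose from 82.6 ± 10.2 to 115 ± 33.1 CPM (edgeR blocked adjusted p = 0.0335). It was the only one of 18 tested members to pass in the blocked fit, while 17 of 18 had higher estimates with a median log2 change of 0.14; adjusted over the list alone 3 rose with the block. Camera gave an adjusted p of 0.00305 (adjusted p = 0.686 with an estimated correlation). The call ended without vehicle 2 (adjusted p = 0.255) and without pair 2 (adjusted p = 0.403). Higher estimates were also common in lists without a call, 12 of 13 reference genes and 20 of 25 core Mediator genes.

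**Figure D4:**
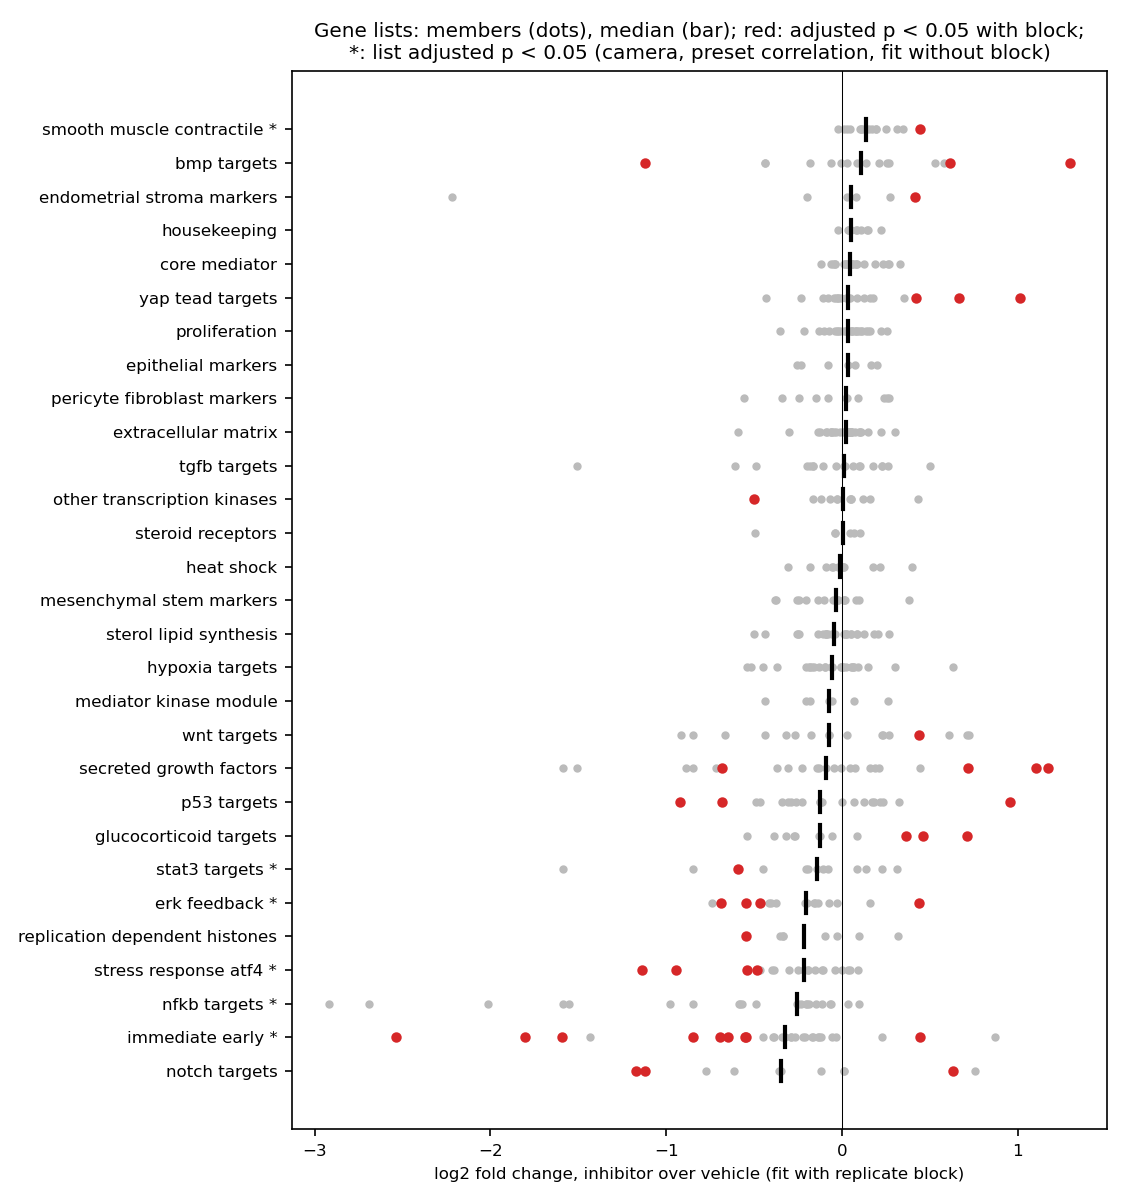
Log2 fold change (inhibitor over vehicle, replicate block) of each tested member of the plotted gene lists, all with at least 5 tested members; bars are list medians, red dots members with an adjusted p below 0.05, and stars the lists with a camera adjusted p below 0.05 in the planned fit. Immediate-early genes hold 8 red dots below 0 and 1 above it.

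Single members of further lists passed in the blocked fit. Among glucocorticoid receptor targets SGK1 (1.64-fold higher, edgeR adjusted p = 2.62e-05), DUSP1 and ERRFI1 rose, 3 of 12 tested. Among p53 targets the kinase PLK2 rose from 53.5 ± 16.4 to 103 ± 26.2 CPM (adjusted p = 1.89e-06), while the pro-apoptotic BBC3 and GDF15 fell, 3 of 22. Among YAP/TEAD targets TGFB2, GADD45B and ANKRD1 rose, 3 of 21. HEXIM1, which holds P-TEFb inactive, fell (-0.50 ± 0.10, adjusted p = 0.00731), as did the linker histone H1F0, while DKK1, a WNT antagonist, and HOXA10 rose. None of these lists had a camera adjusted p below 0.05 in the planned fit or with the replicate block. In other settings some did. The p53 list passed as lower without pair 2 (0.0303), and so did the histone list that holds H1F0 with the stricter filter (0.0380, 6 members). Adjusted over the list alone, with the block, 3 glucocorticoid targets rose and 3 fell, 2 p53 targets rose and 5 fell, and 4 YAP/TEAD targets rose. Outside the lists, TXNIP, an inhibitor of glucose uptake, was 2.88-fold lower (439 ± 142 to 152 ± 50.4 CPM, adjusted p = 1.31e-05), carbonic anhydrase CA2 2.54-fold and ZCCHC12 2.44-fold lower. PPP1R3C, a glycogen-targeting phosphatase subunit, was 1.83-fold higher (adjusted p = 1.31e-05), and TMEM160, PALMD, ANKRD9 and SNHG9 also rose.

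Transcripts of the target complex showed no call. CDK8 was at 14.0 ± 1.60 CPM in vehicle and 16.9 ± 2.58 with inhibitor (log2 change 0.27 ± 0.17, edgeR adjusted p = 1.00), and CDK19 at 42.1 ± 4.61 and 43.9 ± 2.87 (0.06 ± 0.13). CCNC, MED12, MED12L, MED13 and MED13L had log2 changes of -0.06, -0.08, -0.47, -0.21 and -0.18. None of the 7 kinase module genes passed in either fit, by DESeq2 or by limma-voom, nor when adjusted over the list alone; at an unadjusted p below 0.05 there were 0 without and 2 with the block. An inhibitor of kinase activity need not change these transcripts, so they do not check the labels. Of 25 core Mediator subunits, 33 matrix genes, 29 proliferation genes, 28 hypoxia targets, 26 sterol synthesis genes, 19 TGF-β targets, 16 stem cell markers, 13 heat shock genes, 13 reference genes and 6 steroid receptor genes, none passed over all genes in either fit. Adjusted over the list alone, with the block, 2 hypoxia targets rose and 2 fell, 1 TGF-β target rose and 1 fell, and 1 heat shock gene rose. Markers of other cell types gave 1 call: of 7 epithelial and 11 pericyte or fibroblast markers none passed, 4 endothelial and 3 leukocyte markers were measurable and none passed, and HOXA10 was the 1 of 6 endometrial stromal markers that did. Adjusted over the list alone, with the block, 2 pericyte or fibroblast markers rose and 1 fell.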

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

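The block of number 3 alone, the alternatives run within the replicate block, and the length and GC offsets were chosen after the data were seen. Without the block, the count of genes was 1 with RLE factors, library totals, the stricter filter and a non-robust prior, 0 with upper-quartile factors, limma-voom or a 1.2-fold threshold, 2 without a low-count filter, 18 with DESeq2, 180 with the replicate block and 61 with a block of number 3 alone. Leaving out libraries or pairs gave 0 to 38 genes, the 38 without pair 3. Within the block the count was 147 to 234 over the other scalings, tools, priors, the stricter filter and the length and GC offsets, 454 without a low-count filter, 32 above 1.2-fold, and 11 (without pair 2) to 284 (without pair 1). Similar counts did not mean the same genes. Of the 180 calls, 166 were kept with library totals, 140 with offsets from longest transcripts and 122 with offsets from principal transcripts. Of the 180 genes, 30 passed in all 11 settings that kept every library, and 177 kept their sign in all blocked settings. Among genes named above, HES1, GDF15, BBC3, DDIT3 and SNHG9 passed in 0 of the 3 blocked fits with 1 pair left out. NOG, EGR1, KLF2, INHBA, PLK2, DDIT4, TXNIP, CA2 and PPP1R3C passed in all 3. The calls of DUSP6 and HOXA10 held in 4 of the 11 settings and those of DUSP1 and SNHG9 in 5. The 7 lists became 1 with an estimated correlation, 1 in directional fry, and 6 to 14 with libraries left out, the 14 without inhibitor 3. Mixed fry passed 2 lists, of which 1 was among the 7 and the other was the BMP list. With the replicate block mixed fry passed 6, of which 1 was among the camera calls. They were immediate-early (adjusted p = 0.00495), BMP (0.00557), Notch (0.0125), YAP/TEAD (0.0134), WNT and glucocorticoid (0.0476 each). With the replicate block the 7 camera calls became 6, and 0 with an estimated correlation or in directional fry. The replicate block ended the call of the STAT3 list and changed no other; the block of number 3 alone ended it too and added the Notch list. Without vehicle 2 the proliferation list passed as higher (0.24) and the sterol synthesis list as lower (-0.29). The sterol synthesis list changed direction without pair 1 (median log2 change 0.15, and 0.19 with the block) and the proliferation list without vehicle 3 (-0.18). The kinase module had 0 calls in every setting, with and without the block. The cause of these shifts was not tested. In the planned fit, simulated 1.5-fold changes were found in 18.8% of cases, so changes of that size may be missed. Those counts were drawn independently for each library, without the structure that same-numbered libraries share, so the rate need not hold for the real data.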

Other observations

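Further genes that passed in edgeR with the replicate block are given here. They were chosen after their values were seen, and none was tested as part of a group. The insulin receptor substrates diverged: IRS1 rose 1.44-fold and IRS2 1.68-fold (adjusted p = 0.00325 and 0.000215), while IRS4 was 2.75-fold lower (adjusted p = 2.71e-06). ARRDC4, an arrestin-domain relative of TXNIP, fell with it (log2 change -0.69 ± 0.14, adjusted p = 0.0295). BDNF, a secreted growth factor of neurons, rose (95.6 ± 22.8 to 130 ± 37.6 CPM, n = 3), as did FST, which encodes the activin-binding protein follistatin (0.55 ± 0.09). The cation channel genes TRPC4 and TRPC6 rose by log2 changes of 0.56 ± 0.10 and 0.37 ± 0.09, and EDN1, the precursor of the vasoconstrictor endothelin-1, was 2.31-fold higher at a low level. BRD2, PPP1R10 and MIDN fell. The calls of TRPC6 and EDN1 each held in 4 of the 11 settings that kept every library, that of IRS4 in all 11. With 1 pair left out, EDN1 passed in 0, TRPC6 in 1 and IRS4 in 3 of 3 fits.

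In the tests that follow, those on all immediate-early members, on the pairs, with principal transcripts, and of the excess over all genes were chosen after the results they bear on had been seen. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share below 0.05. The real split gave 1 gene and the highest other 332, and 2 splits, the real one included, reached the real count. The split with 332 sets inhibitor 1, inhibitor 2 and vehicle 2 against the rest, which points to a structure of the samples. For lists, the real split gave 7, the highest other 10, and 3 splits, the real one included, reached that count. In other splits preset-correlation camera gave adjusted p values down to 2.63e-13 for the proliferation and 5.37e-13 for the sterol synthesis list. The immediate-early, NF-κB and ATF4 lists passed in other splits too (lowest camera adjusted p = 0.000626, 8.98e-05 and 0.000271). Their values in the real split were lower still, but 10 splits are too few to judge that. With the block, the 4 splits that part every pair are again too few: the real one gave 180 genes and the highest other 1, so that 1 split reached the real count, while for lists the real value of 6 was equalled by others (highest other 6, 3 splits reaching it, the real one included).

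The lower immediate-early genes were weighed against length bias and against a single deviating pair. With offsets for transcript length and GC content the median log2 change of all 31 members, -0.32 before, was -0.32 (SE 0.15) with longest transcripts. With principal transcripts it was -0.34 (SE 0.15), and both lay little more than 2 standard errors below 0. These standard errors, like those of the pairs and sets below, were taken over member genes, which are not independent replicates. The offsets left the median nearly unchanged, which argues against such bias, as modelled, as the whole cause. The same test on the 8 genes that passed as lower (-0.80, SE 0.32) decides nothing, since they were chosen for being low. The first test of whether 1 pair decides the pattern left it open: the medians were below 0 in all 3 pairs, but lay within 2 standard errors of 0 in pair 2 (-0.19, SE 0.16) and pair 3 (-0.30, SE 0.16), and beyond them in pair 1 alone (-0.45, SE 0.17). A second test, chosen after that outcome, found the list still called whichever pair was left out (highest camera adjusted p = 1.1e-06, preset correlation, replicate block), a call that with all pairs is lost with an estimated correlation (adjusted p = 0.514). The same blocked test also called the list in a split other than the real one (camera adjusted p = 0.00627). Keeping the call without a pair therefore says little about whether 1 pair decides the pattern. Whether 1 pair decides the pattern or sets the size of the change stays open, and so does an effect of the inhibitor, the treatment the groups differ by.

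Transcripts of ribosomal proteins and the respiratory chain, a set chosen after calls were seen, had a median log2 change of 0.21 over 147 genes with the block, 15 of them passing as higher, and short transcripts were higher in general (Spearman rho of log2 change with length -0.28 across genes, which are not independent replicates). Length and GC offsets lowered the median to 0.16 (SE 0.02) with longest transcripts and, in a second version made after the first result was seen, to 0.13 (SE 0.02) with principal transcripts; 17 and 10 of the genes then passed, while upward calls over all genes went from 113 to 168 and 135. As the median of all tested genes also moved, to 0.02, the excess over it went from 0.21 to 0.14 and 0.10. Length bias may therefore account for a large part of the rise. The remaining excess cannot exclude it as the whole cause. The set was chosen after calls were seen, and the excess depended on which annotated transcript gave the length. Scaling by library totals left a median of 0.19 (SE 0.02). RNA integrity per library was not analysed here, so a technical difference that favours short transcripts stays open beside an effect of the inhibitor.

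Among the lower NF-κB targets a few members had extreme differences in pair 2 (log2 difference -4.92 for CXCL1 and -3.70 for PTGS2). Without vehicle 2 the mean log2 change of the list was -0.45 (SE 0.09) against -0.86 with all libraries, while the median was -0.32 against -0.24. That library thus enlarged the mean through extreme members but not the median, which was lower without it. The list still passed camera without it (adjusted p = 5.81e-07; adjusted p = 0.553 with an estimated correlation), and 22 of 23 members had lower estimates. High cytokine expression in vehicle 2 may thus account for the size of a few changes but not for the direction of the list. As no member passed over all genes, an effect of the inhibitor on these genes stays open.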
